A study of Homo sapiens with 10 samples.

How the data were processed

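RNA of U266 cells was measured in 10 libraries, 5 with a guide to EFNB2 and 5 with a scrambled control guide, grouped by the genotype field of the labels. Per the labels' protocols, cells were transduced with dCas9-VPR and a guide, selected with blasticidin and puromycin, and libraries were made with a strand-specific kit after poly(A) selection and sequenced as read pairs on a NovaSeq. The submitters' processing notes name GRCh38, STAR 2.27a, Partek and DESeq2 without saying which step each did. The gene annotation and the strand setting used for counting are not given in the sources used here. The authors deposited raw read counts per gene, whole numbers with no normalization, which all main results use. The authors also deposited a normalized signal per gene, which on inspection equals the raw count plus 0.0001, times 1 constant per library (within 0.000497% for counts above 100), and this table served only as an alternative. Rows named only by a number, which read like dates made by a spreadsheet, name no gene and were left out of library sizes and tests; their share of counts was at most 7.00e-05% in any library.

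Counts of 60574 genes were read, and 17834 genes passed the filterByExpr function of edgeR 4.0.16 (R 4.3.3) and were tested. Libraries were scaled by TMM and compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with guide as the only term and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05, and adjusted p-values in the text are from this fit unless a list test is named. The standard error of a log2 fold change is its absolute value over the square root of the F statistic. CPM, as given by edgeR, are counts over the TMM-scaled library size, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 0.0489. Gene lists, 41 in number and fixed before the data were examined like the tests, the filter, the main design and the alternatives named last, were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and, beside it, with a correlation estimated from the residuals. Of the 9 lists that passed with the preset correlation, 0 passed with the estimated one. The fry test, which asks whether a list moves on balance in one direction and does not compare it with other genes, was an alternative. Chromosomes were compared by camera with an estimated correlation. Gene positions came from RefSeq (GRCh38) by symbol or GENCODE 29 by name.

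The genes named in the text follow a rule fixed in advance. It took EFNB2, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between guides (clone-named gene models left out), the 5 smallest p-values in each direction, up to 3 rises and 3 falls from each list that passed and from the lists on Eph signalling, neighbours of EFNB2, STAT5, IL6, the BCL2 family, the cell cycle, plasma and B cells and drug targets, and a few genes named in advance. Of the genes the rule gave, 115 are reported, of which 111 passed the threshold, and some are not reported here. A further 13 are named in the report or the closing part, chosen after their values were seen.

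The steps were tested on simulated data, with counts drawn from the means, library sizes and dispersions of the 17834 tested genes. For the comparison of the guides, 50 genes each were changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 50%, 70%, 82% and 98% of them were recovered. In the simulation 207 genes passed, against 8098 in the data. An adjusted threshold is stricter when fewer genes change, so these shares do not measure how many real changes were found. A list shifted by a known amount was found by camera, together with 1 list that was not shifted, and 5.8% of the gene calls fell on unchanged genes. The shifted list also passed with an estimated correlation. Genes were drawn independently, while the correlation estimated in the data was 0.79 for the G2 and mitosis list. The simulation therefore does not test lists whose genes vary together. At these depths 3 counts in a single library, the limit that a count of 0 allows, correspond to 0.0537 to 0.0627 CPM. Fold changes against a group with no count were set against 3 counts over that group, with the lower end of the 95% exact Poisson interval beside them. Ratios with 1 to 7 counts in the lower group carry 95% exact Poisson intervals. Such intervals cover counting error only, since the reads carry no molecular identifiers that were used here.

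Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals alone, no filter, a filter of at least 1 CPM in 5 libraries, leaving out immunoglobulin genes, the replicate letter as a block, the deposited normalized values on the scale of log2(value + 1) with limma-trend, and leaving out each library in turn. Leaving out chromosome 15 genes and leaving out both A libraries were added after seeing the data.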

Results

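The data were RNA-seq libraries of U266 cells, an established human multiple myeloma line of plasma cell type. The cells carried dCas9-VPR, a Cas9 protein that does not cut DNA and is fused to transcriptional activators, so that a guide RNA placed at a promoter raises transcription there. One group of 5 libraries (A to E) came from cells with a guide to the start of EFNB2, which encodes the ligand ephrin-B2, and the other group of 5 (A to E) from cells with a scrambled guide. The total count per library lay between 47268072 and 56513548, with a mean of 50445497 ± 2882751 (SD, n = 5) for the EFNB2 guide and 54263865 ± 1950010 (SD, n = 5) for the control guide (exact permutation test over 252 splits, two-sided, p = 0.0397). Slightly more genes had at least 1 count with the EFNB2 guide, 26920 ± 86.1 (SD, n = 5) against 26093 ± 109 (SD, n = 5). The labels do not say that the libraries of a guide came from separate cultures or transductions, so p-values measure only the spread between these libraries, whether technical or biological. Libraries of the same guide correlated at r = 0.994 to 0.996 over log2 CPM, and libraries of different guides at 0.983 to 0.986. Pairs of libraries with the same guide differed by more than sampling noise, with chi-square over degrees of freedom from 1.94 to 23.5, so all 10 counted as separate libraries.

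The first comparison asked how far the guide raised its own target. EFNB2 (chromosome 13, 106489745 to 106535662 in GRCh38, minus strand) rose 9.96-fold, from 0.119 CPM ± 0.0509 (SD, n = 5) with the control guide to 1.21 CPM ± 0.198 (SD, n = 5) with the EFNB2 guide. The log2 fold change was 3.32 (SE 0.25) with an adjusted p of 4.68e-08, and 2 SE on either side spanned 7.03-fold to 14.1-fold. All 5 libraries with the EFNB2 guide lay above all 5 controls, and the exact permutation test gave p = 0.0079, two-sided, the smallest that 252 splits allow. EFNB2 remained a weakly expressed gene: its level with the guide lay at the 25.4th percentile of the tested genes, and its 5 libraries held 304 counts in all, against 32 in the controls. The ratio of these summed counts was 10.2 (95% exact Poisson interval 7.09 to 15.2, counting error only), below the 80-fold to 100-fold that the submitters' design text gives for qPCR. Among the genes past the threshold, 69 rose by a larger fold than EFNB2.

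**Figure D1:**
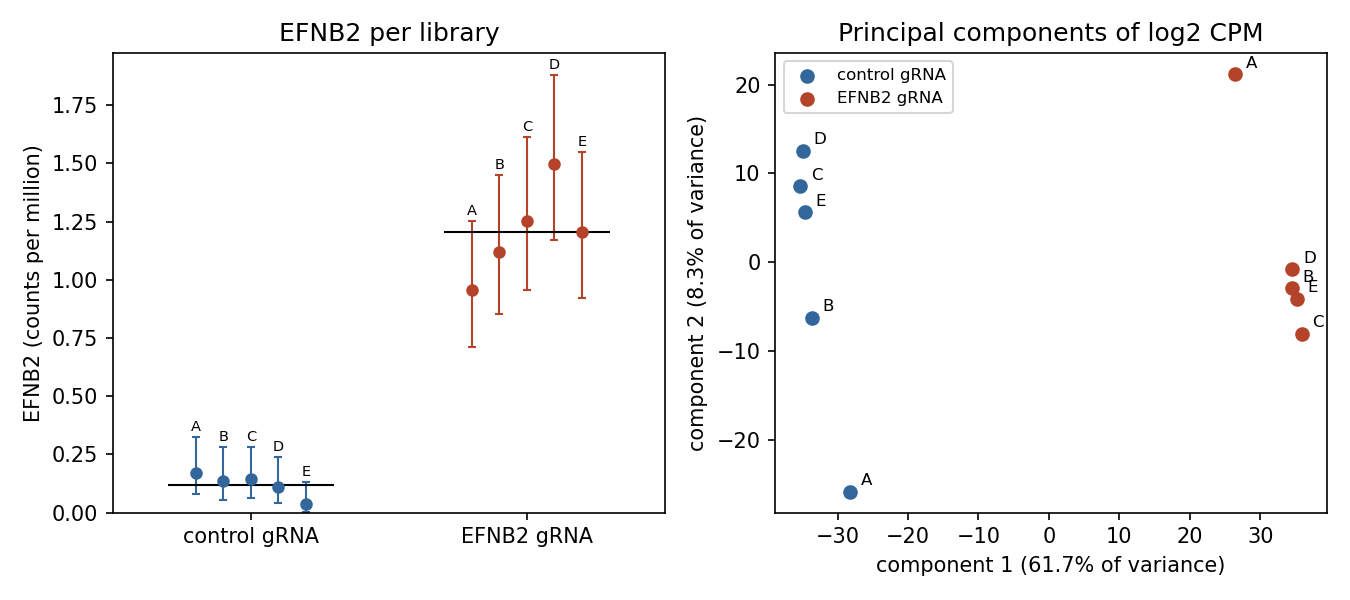
Left, EFNB2 level in CPM in each library (points A to E, bars for the 95% Poisson interval of the count, line for the group mean), where the 5 libraries with the EFNB2 guide average 1.21 CPM and the 5 controls 0.119 CPM. Right, the first and second principal components of log2 CPM over the 17834 tested genes, in which component 1 (61.7% of the variance) separates the guides and the A libraries lie away from the others on component 2 (8.33%).

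Cells with the EFNB2 guide differed from control cells at 8098 genes, mostly by small amounts. Several genes were close to silent in one population and clearly expressed in the other: ANO5 and ANO4, members of the anoctamin family of membrane proteins, the teneurin TENM3, GDAP1L1 and the Notch-binding membrane protein DNER rose from at most 7 counts over the 5 control libraries. Among genes with a mean log2 CPM of at least 1 and no overlap between guides, clone-named models left out, AKAP12 and CYBRD1 fell most. AKAP12 encodes a scaffold protein for protein kinase A and CYBRD1 a membrane ferric reductase. Of 17834 tested genes, 4072 passed an adjusted p of 0.05 as higher and 4026 as lower with the EFNB2 guide. The median absolute log2 fold change of these genes was 0.27, and 79.4% changed less than 1.5-fold. At least 2-fold changes numbered 719, of which 520 were rises and 199 were falls, and 162 genes rose and 32 fell at least 4-fold. The number of at least 2-fold changes was 1434 without a filter. It was 339 with the filter of at least 1 CPM in 5 libraries and 192 on the deposited normalized values. In 5396 genes (30.3%) all libraries of one guide lay above all libraries of the other, where chance gives 0.794%. The first principal component, with 61.7% of the variance, separated the guides, and the A library of each guide lay apart from its group on the second (8.33%).

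Among the largest rises, ANO5 (chromosome 11, 22192473 to 22283357) had no count in the controls and 5.84 CPM ± 1.13 (SD, n = 5) with the EFNB2 guide, at least 527-fold higher when set against a floor of 3 counts over the control group. For GDAP1L1 (chromosome 20, 44247099 to 44280947) the control libraries held 1 count, for ANO4 (chromosome 12, 100717261 to 101128641) 2 and for TENM3 (chromosome 4, 181447613 to 182803024) 3. The ratios of summed counts were 2613 for GDAP1L1 (counting interval 469 to 103200), 2098 for ANO4 (580 to 17330) and 1384 for TENM3 (473 to 6713). DNER (log2 fold change 9.99, SE 0.28), the alternative splicing factor SRRM3 (8.63), the transcription factor CREB3L1 (8.35) and the sorting receptor SORL1 (8.30) came next. The control libraries held 7 counts for DNER, 6 for SRRM3, 5 for CREB3L1 and 5 for SORL1, so these folds and their order are imprecise. Counting intervals of the ratios of summed counts were 543 to 2787 for DNER and 203 to 1205 for SRRM3. They were 158 to 1142 for CREB3L1 and 153 to 1105 for SORL1. The G protein subunit GNAL (6.15) and the phosphatase PXYLP1 (5.74) completed the 10 largest rises within the limits of the naming rule. Adjusted p-values of these 10 genes were at most 3.06e-09. The smallest p-values among rises belonged to IGSF11 (2.66, SE 0.04), PXYLP1, the chromatin organizer SATB1 (from 1.47 to 35.8 CPM), TENM3 and RHOF (1.98, SE 0.04).

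Within the limits of the naming rule, the largest fall was that of AKAP12 (chromosome 6, 151239967 to 151358559). It went from 32.8 CPM ± 4.11 to 0.171 CPM ± 0.103 (SD, n = 5 each), a log2 fold change of -7.54 (SE 0.17). CYBRD1 (-4.40), PAGE1 (-2.98), the homeobox gene LHX8 (-2.54), ZNF729 (-2.13), CLMN (-2.05), ASTN1 (-1.98), ZNF300 (-1.89), GIMAP8 (-1.87) and ARMCX1 (-1.85) followed, each with all libraries of the EFNB2 guide below all controls. ITM2C (-1.14, from 167 to 76.2 CPM) and the potassium channel gene KCNN3 (-1.15, from 210 to 94.3 CPM) were among the 5 falls with the smallest p-values. In the EFNB2 A library, ANO5 stood at 3.86 CPM and ANO4 at 9.35 CPM, below the ranges of 6.09 to 6.71 and 16.2 to 17.9 in the other 4 libraries of the guide. Of the genes named in the report, 13 overlap an annotated gene that holds more counts, and the counts of these genes are less certain. For PXYLP1, SATB1, GNAL, ERCC5 and PRIM1 such a gene lies on the same strand, and for ATF5, BCL2L12, CCNE2, EPHB4, GRIP1, HSPE1, PARP9 and POLR3G only on the opposite strand, where the strand setting of the counting, not given in the sources used here, matters.

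Genes of the ephrin system changed in both directions. In the list of Eph receptors and other ephrins, 3 of 9 tested genes rose and 2 fell, the same counts as adjusted over the list alone. The ligand EFNA2 (1.32, SE 0.21, 0.265 to 0.661 CPM) and the receptor EPHA6 (1.01, SE 0.15, 0.538 to 1.09 CPM), both weakly expressed and named after their values were seen, rose at least 2-fold. EPHB6, a receptor without kinase activity, rose less (0.45, SE 0.07), while EPHA10 (-0.17, adjusted p = 0.0216) and the weakly expressed EPHB1, a receptor for ephrin-B ligands (-1.27, SE 0.32, 0.347 to 0.141 CPM), fell. EPHA10 did not pass without the A library (adjusted p = 0.0557) or the E library (0.0509) of the EFNB2 guide, nor with the replicate block (0.0587) or without both A libraries (0.0895). EPHB4, the main receptor of ephrin-B2 on vessels, was at 6.35 CPM ± 0.422 with the EFNB2 guide and 6.38 CPM ± 0.871 with the control guide (SD, n = 5 each; log2 fold change -0.01, adjusted p = 0.959). Of 30 genes for partners of reverse signalling through B ephrins, 11 rose and 6 fell (12 and 7 adjusted over the list alone, and 8 and 6 of 27 without chromosome 15 genes). They included the kinases PAK1 (0.40) and FYN (0.29) and the protease ADAM10 (0.34) among the rises and RGS3 (-0.78), GRIP1 (-0.63) and NCK2 (-0.47) among the falls, and neither list stood apart from other genes (camera adjusted p = 0.826 and 0.658). Of 11 tested neighbours of EFNB2 on the same chromosome arm, 4 rose and 3 fell (the same adjusted over the list alone). Among those with a mean log2 CPM of at least 1, ERCC5 (0.54), TNFSF13B, which encodes the survival factor BAFF (0.50), and ARGLU1 (0.25) were higher. MYO16 (-0.93), BIVM (-0.30) and TPP2 (-0.15) were lower (camera adjusted p of the list = 0.965). The 1 neighbour that rose at least 2-fold lay below this expression limit and is not named. The Eph list had a median of -0.01 and a mean of 0.16 with a test direction of higher, and the neighbours a median of 0.02 and a mean of 0.09 with a test direction of lower.

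Signalling genes moved in both directions. Of 25 STAT5 targets, 10 rose and 11 fell (the same adjusted over the list alone), and the list's median log2 fold change was -0.02 and its mean 0.10 (camera adjusted p = 0.965). BCL6, the transcriptional repressor of germinal centre B cells (chromosome 3, 187721377 to 187745468), rose from 1.02 CPM ± 0.0578 to 7.96 CPM ± 0.986 (SD, n = 5 each; log2 fold change 2.96, SE 0.11), and EGR1 (0.89) and SOCS3 (0.52) rose less. MYC (chromosome 8, 127735434 to 127742951) fell from 16.2 CPM ± 0.808 to 7.22 CPM ± 1.06 (SD, n = 5 each; log2 fold change -1.16, SE 0.08), and SOCS2 (-0.65) and DUSP5 (-0.37) fell with it. STAT5B was slightly lower (-0.12, adjusted p = 0.00416) and STAT5A did not pass the test (-0.02, adjusted p = 0.879). Of 16 genes of the IL6 and STAT3 axis, 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.826), with TYK2 (0.43), SOCS3 and BCL3 (0.27) higher and the receptor genes IL6R (-0.46) and IL21R (-0.41) and the transcription factor BATF (-0.35) lower. IL6R lay at 882 CPM in the EFNB2 A library, above 735 to 772 CPM in the other 4 of its guide, and at 918 CPM in the control A library, below 1106 to 1134 CPM in the other controls.

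Transcripts for surface proteins that mark plasma cells changed in opposite directions. CD38, an ectoenzyme targeted by antibodies in myeloma (chromosome 4, 15778328 to 15853232), rose from 1.78 CPM ± 0.657 to 8.04 CPM ± 1.09 (SD, n = 5 each; log2 fold change 2.18, SE 0.17), and SLAMF7, also an antibody target, rose by 0.57. SDC1, which encodes the plasma cell marker CD138, fell from 3015 CPM ± 224 to 2121 CPM ± 162 (SD, n = 5 each; -0.51, SE 0.05), and TNFRSF17, which encodes BCMA, fell by 0.38. Over the plasma cell list 8 of 27 genes rose and 11 fell (the same adjusted over the list alone), KLF2 (0.66) among the rises and CADM1 (-0.67) and MZB1 (-0.66) among the falls (camera adjusted p = 0.826). The list of drug targets gave 9 rises and 10 falls among 28 genes (10 and 10 adjusted over the list alone; camera adjusted p = 0.965), with the drug efflux pump ABCG2 higher (0.46) and FKBP5 (-0.28) and FCRL5 (-0.19) lower. In the B cell list 10 of 23 genes rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.658), with BCL6, SPIB (0.29) and CIITA (0.24) higher and BACH2 (-0.74), BLK (-0.66) and BTK (-0.42) lower. The plasma cell list had a median of -0.02 and a mean of 0.03, and the drug target list a median of -0.01 and a mean of 0.12. IRF4, on which myeloma cells depend, was at 647 and 667 CPM and did not pass the test with all libraries (0.04, adjusted p = 0.414), but did without the EFNB2 A library (0.09, adjusted p = 0.00349). Over all settings the adjusted p of IRF4 ran from 0.00114 to 0.792. CCND1 fell slightly (-0.19, from 1959 to 1721 CPM).

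Among genes of the BCL2 family, which control apoptosis, 3 of 17 rose and 8 fell (the same adjusted over the list alone; camera adjusted p = 0.7). The pro-apoptotic members BMF (-0.75, SE 0.04), HRK (-0.63) and BBC3 (-0.40) fell, as did the anti-apoptotic BCL2 (-0.16, adjusted p = 0.0124, and 0.0519 with the replicate block). The anti-apoptotic BCL2L1 rose from 296 to 338 CPM (0.19, SE 0.03), as did BCL2L12 (0.26), and MCL1 did not pass the test (0.05, adjusted p = 0.345).

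Most genes of the cell division lists rose. Of 48 G2 and mitosis genes 47 rose and none fell, with a median log2 fold change of 0.43 (camera adjusted p = 1.49e-16, and 0.779 with an estimated correlation). The cyclin CCNB2 (0.87), the kinesin KIF23 (0.75) and the checkpoint kinase BUB1B (0.67) led among those above the expression minimum. Of 46 S phase genes 37 rose and 2 fell (median 0.19, camera adjusted p = 3.58e-08, and 0.947 with an estimated correlation). The cyclin CCNE2 (0.62) and the helicase BLM (0.59) were higher, and the primase subunit PRIM1 (-0.25) and, narrowly, MCM6 (-0.07, adjusted p = 0.0461) were lower. MCM6 did not pass when any 1 of the 10 libraries was left out, nor with library totals alone, no filter, the filter of at least 1 CPM in 5 libraries, the replicate block or chromosome 15 genes left out (adjusted p from 0.0502 to 0.148). All 16 tested replication-dependent histone genes rose, with a median of 0.81 (camera adjusted p = 3.06e-09, and 0.341 with an estimated correlation), among them H2BC11 (1.17), H2BC21 (1.16) and H1-4 (1.12). Of these genes CCNB2, KIF23, BUB1B and BLM lie on chromosome 15, and without the genes of that chromosome 43 of 44 G2 and mitosis genes and 33 of 42 S phase genes rose.

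Most genes for ribosomal proteins were slightly lower. Of 73 genes for cytosolic ribosomal proteins 65 fell and 1 rose, with a median of -0.19 (camera adjusted p = 2.18e-16, and 0.779 with an estimated correlation). RPL35A (-0.47, SE 0.03), RPL23 (-0.37) and RPS4X (-0.34) fell most among them, and RPL4, which lies on chromosome 15, rose (0.11). Of 38 genes of the ATF4 amino acid response 20 fell and 4 rose (median -0.11, camera adjusted p = 0.003, and 0.947 with an estimated correlation), with JDP2 (-0.66), DDIT4 (-0.59) and the mitochondrial folate enzyme ALDH1L2 (-0.51) lower and ATF5 (0.51), ATF3 (0.28) and GARS1 (0.11) higher. The list of MYC and ribosome biogenesis genes had 20 falls and 5 rises among 42 (median -0.04, camera adjusted p = 0.0374, and 0.779 with an estimated correlation). Beside MYC itself, the polymerase III subunit POLR3G (-0.73) and GNL3L (-0.20) were lower and GNL3 (0.19), TCOF1 (0.17) and HSPE1 (0.16) higher, and HSPE1 did not pass without the D or E library of the EFNB2 guide or the B, C or D library of the controls, without a filter or on the deposited normalized values (adjusted p from 0.0585 to 0.0942). The MYC list did not pass without chromosome 15 genes (adjusted p = 0.0634), with the replicate block (0.0532), with the filter of at least 1 CPM in 5 libraries (0.113) or without the B, C or E library of the EFNB2 guide or the B or E library of the controls, with adjusted p from 0.0283 to 0.113 over all settings with the preset correlation.

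Of 25 cholesterol synthesis genes 20 rose and 1, PMVK (-0.31), fell, with a median of 0.24 (camera adjusted p = 1.46e-05, and 0.779 with an estimated correlation). INSIG1, a regulator of the pathway held in the endoplasmic reticulum, was among the rises (0.67, SE 0.05). In the interferon response list 20 of 41 genes rose and 5 fell (23 and 5 adjusted over the list alone; median 0.24, camera adjusted p = 0.0183, and 0.967 with an estimated correlation). Its members divided: PARP9 (1.70), its partner DTX3L (1.10) and the deubiquitinase-like USP18 (1.14) rose, while the antiviral genes MX2 (-0.85), OAS2 (-0.69) and OAS1 (-0.48) fell. Of 30 MAPK immediate-early and feedback genes 16 rose and 7 fell (17 and 7 adjusted over the list alone; median 0.22, camera adjusted p = 0.0388, and 0.779 with an estimated correlation), with the feedback inhibitors SPRY1 (1.39) and SPRED1 (0.73) and EGR1 higher and MYC, EGR2 (-0.58) and DUSP5 lower. Without both A libraries the interferon list (adjusted p = 0.0816) and the MAPK list (adjusted p = 0.22) did not pass. With the filter of at least 1 CPM in 5 libraries neither passed (0.0616 each). The interferon list also failed without the control A library (0.0763), with adjusted p from 0.00553 to 0.0816 over all settings with the preset correlation. The MAPK list also failed without the A library (0.132) or E library (0.0531) of the EFNB2 guide, without the A (0.0738), B (0.0703) or E (0.0529) library of the controls and without chromosome 15 genes (0.0544), over a range of 0.0246 to 0.22. In addition, OAS1 and OAS2 in each A library lay between the other libraries of its guide and those of the other guide. For the other lists described in this and both preceding paragraphs the counts were the same adjusted over the list alone.

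**Figure D2:**
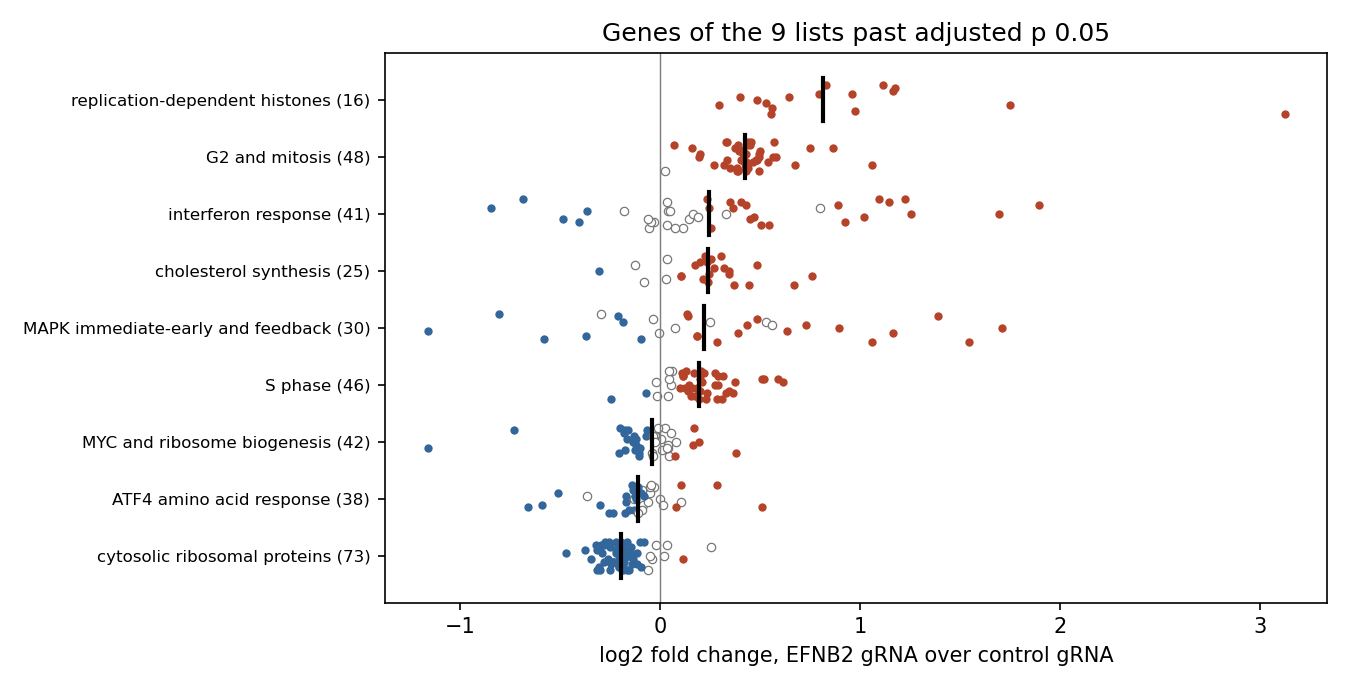
Log2 fold change (EFNB2 guide over control guide) of each tested gene in the 9 gene lists past an adjusted p of 0.05 by camera with the preset correlation (0 of them with an estimated correlation), with the number of tested genes in parentheses. Filled points passed the adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars are list medians, from 0.81 for histones to -0.19 for ribosomal proteins.

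The remaining 32 of the 41 lists did not stand apart from other genes, with camera adjusted p from 0.385 to 0.965. Among markers of other cell types, 3 of 7 tested T and NK cell markers rose and 2 fell, 1 of 4 myeloid markers rose, none of 3 endothelial markers passed, 2 of 6 fibroblast and stromal markers rose and 2 fell, 2 of 5 epithelial markers rose and 1 of 3 erythroid markers fell. Adjusted over the list alone these counts differed only for erythroid markers, with 1 higher and 1 lower. By fry, which does not compare a list with other genes, the T and NK cell (adjusted p = 0.000222), epithelial (0.00519) and myeloid markers (0.0393) moved higher on balance. Mitochondrially encoded genes made up 4.03% ± 0.0931 of counts with the EFNB2 guide and 3.96% ± 0.471 with the control guide (SD, n = 5 each; exact permutation test, two-sided, p = 0.754).

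Genes of chromosome 15 were higher as a whole with the EFNB2 guide. Their median log2 fold change was 0.31, and 398 of them passed the threshold as higher and 27 as lower, so that 93.7% of the calls on this chromosome were rises. It was the only 1 of 23 chromosomes that stood apart from the rest (camera with an estimated correlation, adjusted p = 0.000162). Medians of the others lay between -0.03 and 0.05. The chromosome 15 genes with higher values included ADAM10 and SPRED1 named above, while BMF fell. With these genes left out, 7639 genes passed the threshold, 3727 higher and 3912 lower, and the G2 and mitosis list kept a median of 0.42.

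A scan with windows of 25 neighbouring genes, chosen after the shift of chromosome 15 was seen, showed where along the chromosomes values moved together. Over 10949 genes with a mean log2 CPM of at least 2, windows passed the largest of 1000 shuffled gene orders in 6 stretches. On chromosome 15, 3 stretches covered nearly the whole length from 20408396 to 101976605, with medians of 0.32, 0.28 and 0.31. On chromosome 12, 101 genes between 115958576 and 133214832 had a median of 0.30, and 90.1% of them were positive; RHOF lies in this stretch. At the end of chromosome 3, 29 genes between 195514428 and 198080693 had a median of -0.34, and RPL35A lies there. On chromosome 6 the stretch from 24667077 to 28137316 held 67 tested genes, of which 27 were histone genes with a median of 0.56 and the other 40 had a median of 0.10. Every library with the EFNB2 guide showed the chromosome 12 shift, by 0.31 to 0.37 against the control mean, and the chromosome 3 shift, by -0.33 to -0.27. Single control libraries lay between -0.02 and 0.00375 in both, near 0 in part because their own mean is the reference. The stretches were picked from these same libraries.

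**Figure D3:**
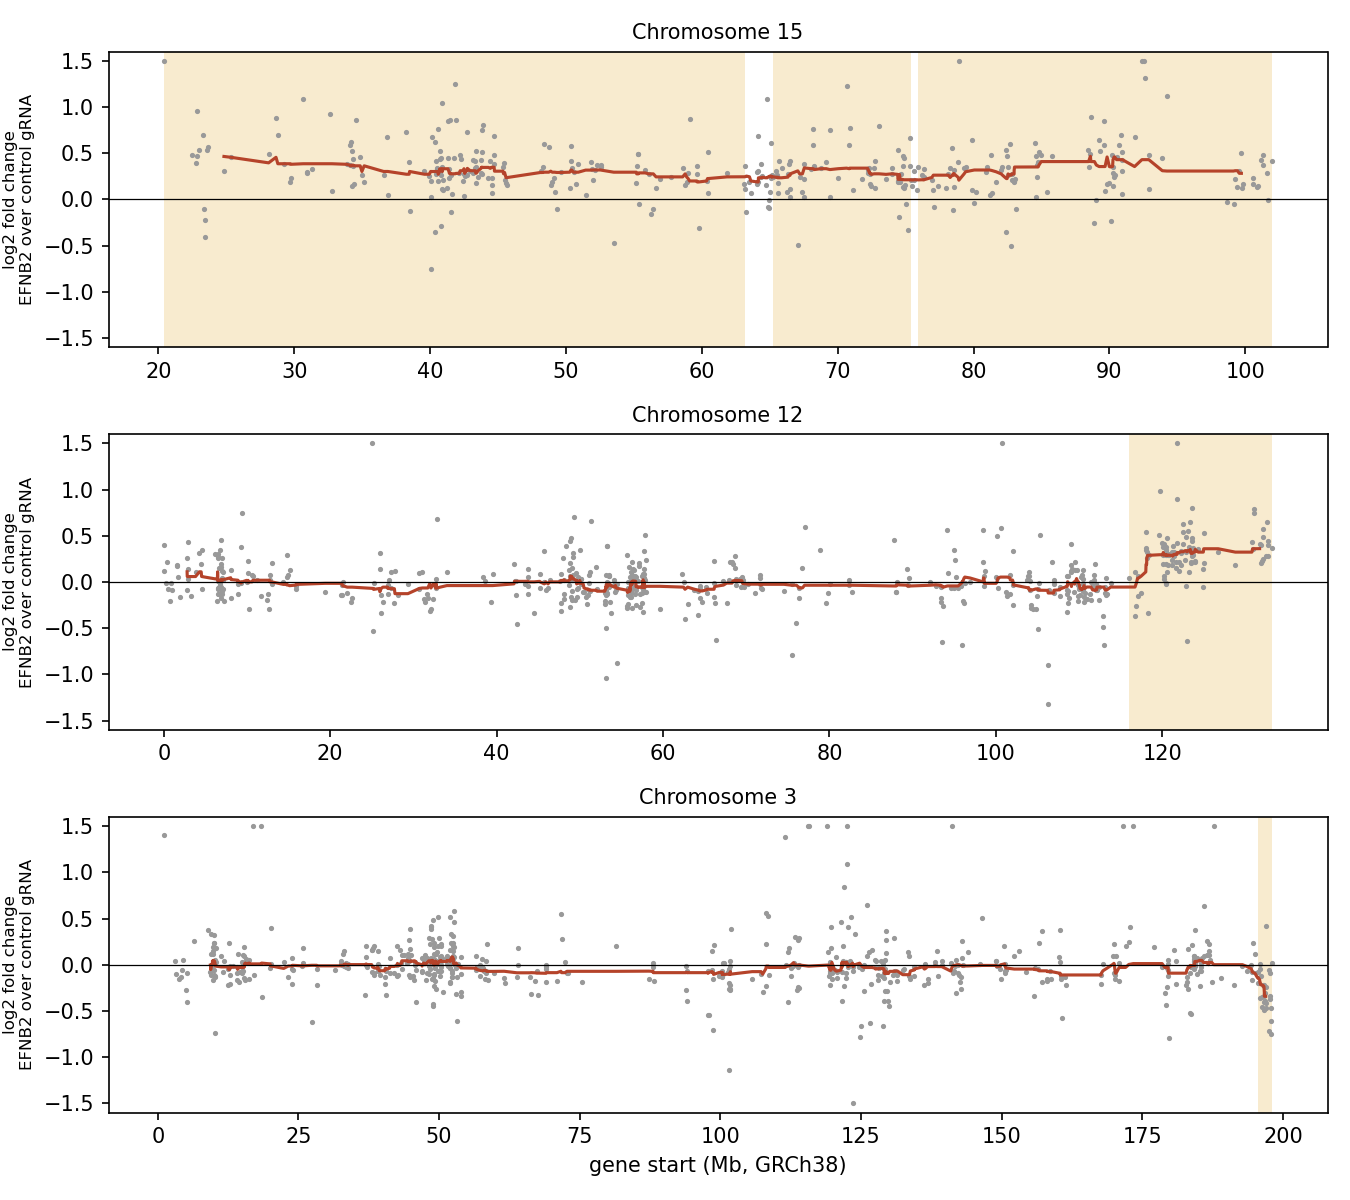
Log2 fold change (EFNB2 guide over control guide) of genes with a mean log2 CPM of at least 2 against gene start in Mb (GRCh38) on chromosomes 15, 12 and 3. Grey points are genes, with values beyond the axis drawn at its edge, the red line is the median of 25 neighbouring genes, and shaded stretches passed the shuffled orders: nearly all of chromosome 15 (medians 0.28 to 0.32), the end of chromosome 12 (0.30) and the end of chromosome 3 (-0.34).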

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

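The comparison of the A libraries with the rest of their groups was chosen after the values were seen; the search for single libraries far from their group was planned. In 270 groups of 5 libraries (named genes and library measures, per guide), 48 had 1 library whose gap to the nearest other took most of the group's range. Chance gives about 1 in 20, or 13.5, for independent groups of normally distributed values. The groups here share the same 10 libraries, so 1 shifted library can flag many of them. For genes with almost no counts, such as GDAP1L1 and SRRM3 in the controls, count steps alone can flag a library. The flagged library was an A library in 44 of the 48.

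With the EFNB2 guide, the A library stood below the others for ANO5 (3.86 CPM), ANO4 (9.35), DNER (18.8), GNAL (3.66), ARGLU1 (219), BCL2L1 (318), KIF23 (131), BUB1B (108.5), CD38 (6.15), KLF2 (24.5), INSIG1 (63.1), H2BC11 (14.97), H2BC21 (30.1), IRF4 (583.5), EPHB4 (5.62) and PLEK (30.2 CPM, chosen after its value was seen). It stood above them for MYC (9.09 CPM), DUSP5 (112), IL6R (882), IL21R (11.3), SDC1 (2410), OAS2 (324), OAS1 (525), BCL2 (296) and UCHL1 (596, chosen after its value was seen). The A library of the control guide stood above the other controls for GDAP1L1 (0.0189 CPM, a single count), SRRM3 (0.0378), ZNF300 (16.8), BUB1B (85.3), CD38 (2.93), POLR3G (15.8), GARS1 (397), ALDH1L2 (79.8) and UCHL1 (622), and below them for IL6R (918 CPM), BMF (93.0), CADM1 (205), OAS2 (354), OAS1 (551.5), BCL2 (265.5) and MCL1 (1070).

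On the first principal component the A libraries lay nearer to the other guide, at 26.4 against 34.6 to 35.9 for the EFNB2 guide and at -28.2 against -35.3 to -33.6 for the control guide. On the second the EFNB2 A library lay at 21.2 and its group at -8.04 to -0.8. Among 138 genes changed at least 2-fold with a mean log2 CPM of at least 2, the EFNB2 A library lay on the control side of its group's other libraries for 89 and the control A library on the EFNB2 side for 79. The median share of the gap between guides that was lost was 4.89% and 4.05%. GDAP1L1 at 10.5 CPM and TENM3 at 16.2 CPM were not lower in the EFNB2 A library than in the other 4 of its guide, which averaged 9.33 CPM ± 0.605 and 14.97 CPM ± 0.782 (SD, n = 4).

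Outside the A libraries, MZB1 stood at 4.99 CPM in the control D library, RPL35A at 415 CPM in the control C library, and SPRED1 at 21.7 CPM and EGR2 at 2.69 CPM in the EFNB2 E library.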

How the results depend on the processing

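Leaving out chromosome 15 genes and leaving out both A libraries were chosen after the data were seen; the other settings were planned. The rise of EFNB2 passed the threshold in every setting that tested it, with log2 fold changes of 3.09 to 3.55 on counts and 0.97 on log2(value + 1) of the deposited normalized values, a scale that compresses weakly expressed genes. The filter of at least 1 CPM in 5 libraries removed EFNB2. The count of changed genes lay between 6762 (replicate block) and 9854 (both A libraries left out), and with single libraries left out between 7261 and 9130. The letters A to E did not pair the libraries: deviations of libraries with the same letter correlated at -0.24 to -0.003, each letter correlated better with another letter than with its own, and the replicate block lowered the count from 8098 to 6762. At least 2-fold changes numbered 719, and 1434 without a filter, which adds weakly expressed genes, 339 with the filter of at least 1 CPM in 5 libraries, which removes them, and 192 on the deposited normalized values. The share of rises among the calls was 50.3%, 54.2% with library totals only and 43.1% on the deposited normalized values, and no scaling moved the median gene by more than 0.03 on the log2 scale. The number of lists past the threshold was 9, and 0 with a correlation estimated per list, which allows for genes of a list varying together, and 24 with fry, which asks another question; the filter of at least 1 CPM in 5 libraries gave 6 and leaving out single libraries 7 to 9. Camera with the preset correlation was run in 15 alternative settings, the main one not counted. The lists of G2 and mitosis, S phase, histones, cholesterol synthesis, ribosomal proteins and the ATF4 response passed in all 15. The interferon list passed in 12 of them and the MAPK and MYC lists in 7 each. Of 2656 pairs of a named gene and a setting, 2626 kept their direction and side of the threshold, 27 lost the threshold, 3 gained it and 0 reversed. The genes concerned were MCM6 (15 settings), HSPE1 (7), EPHA10 (4), IRF4 (2), UCHL1 (1, without both A libraries) and BCL2 (1, adjusted p = 0.0519 with the replicate block); the cause was not tested.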

Other observations

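The tests of the number of chromosome 15 copies and of the share of positive genes on that chromosome were chosen after the result was seen, as was the scan that gave the ends of chromosomes 12 and 3 and as were the levels of all listed neural markers and the genes named in the next paragraph; the other tests here were set out before their results were seen.

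Single genes of the adhesion and axon guidance lists changed, while neither list stood apart from other genes. In the adhesion and homing list 11 of 35 genes rose and 13 fell (11 and 14 adjusted over the list alone; median -0.00, mean 0.17, camera adjusted p = 0.965). S1PR1, a receptor that guides lymphocytes out of tissues, rose from 0.45 to 3.76 CPM (log2 fold change 3.06, SE 0.13) and the laminin-binding integrin ITGA6 by 1.36, while the hyaluronan receptor CD44 (-0.67, SE 0.03) and the tetraspanin CD82 (-1.13, SE 0.14) fell. Among axon guidance genes other than Eph, 11 of 23 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.385), with the plexin PLXNA4 higher by 5.18 (SE 0.25) and the semaphorin SEMA4C lower (-1.58, SE 0.10). Without chromosome 15 genes, 8 of 20 genes of this list rose and 5 fell (camera adjusted p = 0.821). Elsewhere PLEK rose from 4.07 to 35.3 CPM (3.12, SE 0.08), the chemokine CCL4 fell from 9.28 to 2.77 CPM (-1.74, SE 0.09) and the cell cycle inhibitor CDKN1C from 2.02 to 0.633 CPM (-1.67, SE 0.18).

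Genes of chromosome 15 lay higher with the EFNB2 guide by a median of 0.29 over 367 genes above the expression minimum. A correction of each library for GC content and transcript length left the chromosome 0.31 above the others, as before it, which argues against a sequence bias. All 17 bins of 5 Mb with at least 5 genes had a median above 0, in every library with the EFNB2 guide. The chromosome was picked for its shift, so this in part restates it. The bin medians ran from 0.151 to 0.475, and whether they differ beyond the spread of their genes was not tested. Genes of low, middle and high expression had medians of 0.31, 0.30 and 0.28. A candidate explanation is an additional copy of chromosome 15 in all or some of the cells with the EFNB2 guide: in all cells, 5 copies against 4 would give 0.32, 4 against 3 would give 0.415 and 3 against 2 would give 0.585, and in some of the cells less. DNA and the number of copies in the control cells were not analysed here, so this explanation stays a hypothesis, and regulation of the genes without a change in copies stays open too: 90.7% of them were positive, against at most 55.0% on any other chromosome, but the chromosome was picked for its shift, so this share excludes nothing.

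Cell cycle and histone lists lay higher and ribosomal proteins lower with the EFNB2 guide by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.779 for G2 and mitosis, 0.947 for S phase, 0.341 for histones and 0.779 for ribosomal proteins). Without chromosome 15 and the shifted ends of chromosomes 12 and 3 the median of the G2 and mitosis list was 0.42, against 0.43 with them. Of its 48 tested genes 4 lie in these regions, so copies of the list genes themselves do not account for the median. Effects of these regions on genes elsewhere were not tested. After the correction for GC content and length the median was 0.375, so such a bias does not account for it either. Genes taken as other RNAs without a poly(A) tail had a median log2 fold change of 0.26 (bootstrap interval over genes, not libraries, 0.09 to 0.43). This median lay between the bounds set in advance from the histone median of 0.81. The set held only RN7SL1 and genes with names beginning in RNU, since the other RNAs planned for it were not among the tested genes. Most of the RNU names end in P, as names of pseudogenes do, so their counts may not stem from RNAs without a poly(A) tail. Most genes of the set lay below 1 CPM, and they moved in both directions. Above 1 CPM in the controls were only RN7SL1, which rose (0.34, 15.2 to 19.2 CPM), and RNU6-1, which fell (-2.01, 2.12 to 0.525 CPM). A weaker poly(A) selection therefore cannot be told apart from a change in histone transcripts. The correction for GC content and length was void for histones, whose genes had no sequence value under their current names. A difference in growth between the populations may remain for the cell cycle lists, with or without ephrin-B2 as its origin, and was not tested.

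The guides differed at 8098 genes. In 100 of the 126 splits of the libraries into 5 and 5, the real one included, 1 reached 8098 genes, the real split. The highest other gave 0 with edgeR (5155 at an unadjusted p of 0.05, against 9272 for the real split). Every other split mixes the guides, which widens the spread within its groups, so this result restates that the libraries separate by guide. It cannot exclude a chance difference between the populations, since the labels name no separate cultures. With every library thinned to the smallest total, 7983 genes passed, which argues against depth. RNA from neural cells might have brought genes such as DNER and TENM3: of 12 tested neural markers 5 were higher and 2 lower, and 8.33% (SNAP25 alone, from 1.70 to 6.82 CPM) at least 2-fold higher, while UCHL1, at 588 CPM in the controls and 568 CPM with the EFNB2 guide, is too abundant in these cells to show a small share. Over all 30 listed markers the median rise was 0.0129 CPM and the largest 5.14 CPM, and 23 stayed under 1 CPM, against 28.9 CPM for DNER and 15.2 CPM for TENM3, which argues against neural RNA as their source. An effect of ephrin-B2, of the guide at other sites and of separately selected populations stay open, since each guide is one group in this design.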
